A study of Homo sapiens with 36 samples.

How the data were processed

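Gene expression was measured in 36 samples of human hepatocytes made from induced pluripotent stem cells (iCell Hepatocytes, a commercial product), exposed to silver nanoparticles or not exposed. Per the labels, 100 ng of RNA per sample was labelled with a 3' in vitro transcription kit and hybridized to an oligonucleotide array. Batch 1 held 15 arrays in 5 groups and batch 2 held 21 arrays in 7 groups, with 3 arrays in each of the 12 groups, which the titles call biological replicates. The titles give the concentrations in mg/ml and the design text and treatment protocol give the same figures in µg/ml; µg/ml was used.

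The deposited values are normalized log2 signals, 1 per probe set and array, between 2.37 and 15.11 over 49395 probe sets. The submitters' processing notes name the Transcriptome Analysis Console, without a version. The normalization method, the background correction and the genome build are not given in the sources used here. No further transformation was applied. For arrays there is no count behind a value, and the number of arrays limits the precision.

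Probe sets were named from the platform's annotation: 44988 carried exactly 1 gene symbol, 1832 carried several and 2569 were not listed, and 44961 of the first kind matched a gene name in the reference annotation. Each of 18132 genes was represented by its probe set with the highest mean over all arrays, leaving out the manufacturer's control probe sets. Genes whose highest group mean did not exceed the 40th percentile of all values (log2 value 5.695) were left out, which removed 5572 and left 12560. A gene could therefore pass through an exposed group alone. Of these, 3235 had 1 probe set and 9325 had several.

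A linear model with a mean for each group was fitted within each batch with limma (lmFit and eBayes), and each exposed group was compared with the control arrays of its batch. Genes were called at an adjusted p (Benjamini-Hochberg, over all genes tested) under 0.05. A moderated F test covered all exposed groups of a batch. The exposure at 5 µg/ml, present in both batches, was compared in a fit of 12 arrays with an interaction term. The onset of a gene was the lowest concentration from which it stayed called with the same sign up to the highest concentration of its batch.

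There were 29 gene lists with 474 genes, of which 433 were on the array and 394 were tested. They were tested with camera at a preset correlation of 0.01, adjusted over 290 tests of lists and comparisons. The lists covered metallothioneins and zinc export, the NRF2 and heat shock responses, ATF4 targets, endoplasmic reticulum chaperones, p53 targets, cell cycle, secreted hepatocyte proteins, xenobiotic metabolism, aryl hydrocarbon receptor targets, cholesterol biosynthesis, fatty acid oxidation, bile acids, NF-kB targets, acute phase proteins, immediate early genes, oxidative phosphorylation, proteasome, autophagy, hypoxia and glycolysis, interferon response, iron, selenium and copper handling. Markers of cholangiocytes, stellate cells and fibroblasts, endothelium, macrophages and pluripotent or fetal cells were included. A further 6 lists were written after the results were seen and appear only among the other observations.

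The groups, comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. For 25 µg/ml and for 5 µg/ml in each batch, the rule named the 10 genes with the largest rise and the 10 with the largest fall among called genes whose arrays did not overlap between the groups. It also named up to 3 called members of each list with the largest change, or the member with the lowest p where no member was called. In every group it named MT1X, MT1G, MT2A, HMOX1, HSPA1A, DNAJB1, DDIT3, CDKN1A, CYP3A4 and ALB, and at the other concentrations up to 5 called genes per direction. For the difference between batches it named up to 5 called genes per sign with the lowest adjusted p. HSPA1A had no probe set of its own, so the probe sets it shares with HSPA1B are given.

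Alternatives were all 36 arrays in 1 fit, a fit of only the groups compared, a stricter filter at the 60th percentile (log2 value 7.098), no filter, centring of arrays on their medians, a further quantile normalization, and a block for the replicate number. Others were the mean of all probe sets of a gene, leaving out each array in turn, an adjusted p under 0.01, a change of at least 2-fold, eBayes with trend and robust options, and camera with an estimated correlation. Leaving out the array of each batch that correlated least with its own group was added after seeing the data.

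The procedure was tested on simulated data of 12560 genes. With 50 genes shifted by each size, a comparison in batch 1 called 42% of those shifted by 0.25 on the log2 scale, 92% at 0.5 and 100% at 1, and 0.0728% of unshifted genes. The interaction term called 0% at 0.25, 64% at 0.5 and 96% at 1. Camera called the shifted list in 20 of 20 draws and called any list without a shift in 1 of 20. The simulated genes varied independently, so these draws do not test camera where the genes of a list are correlated. Calculations used R 4.3.3 with limma 3.58.1 and the data.table package (version 1.17.8), and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.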

Results

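Human hepatocytes made from induced pluripotent stem cells, a commercial cell product, were exposed for 24 h, from day 8 of culture, to silver nanoparticles with a nominal diameter of 20 nm. Gene expression was measured on 36 oligonucleotide arrays. Batch 1 held 5 groups (0, 5, 10, 20 and 25 µg/ml) and batch 2 held 7 groups, with 3 replicate arrays in each group. Batch 2 had a control, 3 groups under 0.5 µg/ml (0.01, 0.05 and 0.1 µg/ml) and groups at 0.5, 1 and 5 µg/ml. The sample titles write the same concentrations in mg/ml, whereas the design text and the treatment protocol give µg/ml, which is used here. Values were normalized log2 signals, and 12560 genes with 1 probe set each were tested against the control arrays of the same batch with limma. The series asks how the transcriptome responds over a range of concentrations, and 5 µg/ml is the only exposure present in both batches. The number of arrays limits the precision of every comparison, and the p-values measure only the spread between these replicates.

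At 25 µg/ml, the highest concentration, genes that bind metals, refold proteins and break down heme were among those with the largest rises. MT1G, a metallothionein that binds zinc, copper and silver through cysteines, rose 293-fold, from a log2 signal of 6.57 ± 0.078 in the controls to 14.76 ± 0.013 (SD, n = 3 each; limma adjusted p = 7.85e-21). HSPA6, a strictly stress-inducible member of the HSP70 chaperone family, rose 200-fold from 5.10 ± 0.22 to 12.74 ± 0.16 (SD, n = 3 each). HMOX1, the heme oxygenase, rose 57.9-fold from 7.04 ± 0.033 to 12.90 ± 0.090. Genes of differentiated hepatocytes fell: CYP3A4, a major drug-metabolizing cytochrome, dropped from 11.01 ± 0.057 to 7.45 ± 0.33 (8.5% of the control). ARG1, the arginase of the urea cycle, dropped from 11.10 ± 0.078 to 6.79 ± 0.41 (5.04% of the control). The signal of ALB, the most abundant plasma protein, was 15.05 ± 0.021 in the controls and 14.95 ± 0.0026 at 25 µg/ml, a difference that missed the threshold (adjusted p = 0.0522). Both levels, and that of MT1G at 25 µg/ml, lie near the top of the array's range (highest value 15.11), where a change would be compressed, so the fold of MT1G is approximate too.

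In total 8638 of the 12560 genes (68.8%) were called at 25 µg/ml by limma at an adjusted p under 0.05, 4004 higher and 4634 lower. Of these, 1697 changed by at least 2-fold (841 higher, 856 lower). The 3 exposed arrays lay beyond the 3 control arrays for 70.8% of genes, where chance gives 10%. Besides the metallothioneins, HSPA6 and HMOX1, the genes with the largest rises included MMP10, a matrix metalloproteinase (69.3-fold, log2 change 6.12, SE 0.14), and GAL, the precursor of the neuropeptide galanin (41.5-fold, log2 change 5.38, SE 0.12). The largest falls were in VCAM1, a cell adhesion molecule (4.52% of the control), TDO2, which opens the ring of tryptophan (4.67%), PPP1R3C, a glycogen-targeting phosphatase subunit (4.89%), and ACOT12, an acetyl-CoA hydrolase (4.98%). Close to these were AKR1D1, a steroid reductase of bile acid synthesis (5.05%), SLC38A4, an amino acid transporter (5.84%), LEAP2, a liver peptide that antagonizes the ghrelin receptor (5.85%), DIO1, a selenoenzyme that converts thyroid hormone (6.24%), and SULT2A1, a sulfotransferase of steroids and bile acids (6.78%). At 25 µg/ml ACOT12, AKR1D1, SLC38A4, DIO1, SULT2A1, CYP8B1 and IFIT2 lay under the filter value of 5.695, as did ROBO2, APELA and DIO1 at 20 µg/ml, LGALS2 at 5 and 10 µg/ml and CDC20 and ESRRG at 1 µg/ml. Their percentages of the control are therefore approximate.

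All 10 measured members of the metallothionein and zinc export list rose at 25 µg/ml, also when adjusted over the list alone, with a median log2 change of 5.33 (camera adjusted p = 3.03e-09; adjusted p = 0.0361 with an estimated correlation). MT1H rose 177-fold, MT1M 135-fold and MT1X 75.6-fold. Probe sets of this gene family can cross-hybridize, so the assignment to single family members is uncertain. Of the heat shock response list 23 of 23 members rose, the same number adjusted over the list alone, with a median of 1.3 (camera adjusted p = 3.81e-12; adjusted p = 0.103 with an estimated correlation). CRYAB, a small heat shock protein, rose 16.2-fold, HSPA1B 15.3-fold and DNAJB1, an HSP40 co-chaperone, 4.40-fold. HSPA1A was covered only by probe sets shared with HSPA1B, and the values of these 4 probe sets lay between 2.90 and 4.07. Of the NRF2 oxidative stress list 20 of 23 members rose and 2 fell, the same numbers adjusted over the list alone (median 0.74, camera adjusted p = 2.24e-07; adjusted p = 0.152 with an estimated correlation). They included AKR1B10, an aldo-keto reductase (10.9-fold), and SLC7A11, the cystine transporter that feeds glutathione synthesis (5.35-fold).

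Of the proteasome list 22 of 23 subunits rose (23 adjusted over the list alone; median 0.67, camera adjusted p = 1.87e-08; adjusted p = 0.136 with an estimated correlation). The largest rises were in PSMD2 (3.88-fold), PSMD12 (3.02-fold) and PSMD14 (2.41-fold) of the regulatory particle. Of the autophagy and lysosome list 11 of 19 members rose and 4 fell, also adjusted over the list alone (median 0.18, camera adjusted p = 0.0619). Here MAP1LC3B, which coats autophagosomes, rose 2.87-fold and SQSTM1, a receptor for ubiquitinated cargo, 2.22-fold. In the list of ATF4 targets, genes of the integrated stress response, 11 of 17 rose and 2 fell, the same adjusted over the list alone (median 0.90, camera adjusted p = 0.00385; adjusted p = 0.229 with an estimated correlation). SLC7A5, a transporter of large neutral amino acids, rose 6.61-fold and STC2, a secreted stress glycoprotein, 4.50-fold, whereas PHGDH, the first enzyme of serine synthesis, fell to 19.5% of the control. DDIT3, the stress transcription factor CHOP, had a log2 change of 0.12 (SE 0.095, adjusted p = 0.268). Of 16 endoplasmic reticulum chaperone genes 14 fell and 1 rose, also adjusted over the list alone (median -0.59, camera adjusted p = 4.1e-04; adjusted p = 0.172 with an estimated correlation). Among them were CRELD2 (46.7%), XBP1, a transcription factor of the unfolded protein response (47.4%), and the disulfide isomerase PDIA4 (48.1% of the control).

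Genes of cell division and early growth signalling were also higher. In the cell cycle list 14 of 21 genes rose and 3 fell, the same adjusted over the list alone (median 1.31, camera adjusted p = 4.17e-04; adjusted p = 0.0463 with an estimated correlation). TTK, a kinase of the spindle checkpoint, rose 10.7-fold, BUB1, another checkpoint kinase, 7.23-fold and TPX2, a spindle assembly factor, 6.32-fold. Their control signals (4.77, 3.38 and 5.04) lay under the filter value of 5.695, as did those of HSPA6, MMP10, GAL and MT1M, so these folds are approximate. Of the immediate early genes 10 of 12 rose and 1 fell, also adjusted over the list alone (median 1.07, camera adjusted p = 8.4e-05; adjusted p = 0.0396 with an estimated correlation). FOS rose 3.66-fold, MAFF 2.93-fold and FOSL1 2.83-fold. Targets of p53 moved both ways: 7 of 21 rose and 9 fell, the same adjusted over the list alone (median -0.060, camera adjusted p = 0.947). GADD45A, a growth arrest gene, was 2.55-fold higher and CDKN1A, the cell cycle inhibitor p21, 1.74-fold higher. TP53INP1 and SESN1 were at 37.6% and 40.3% of the control.

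At 25 µg/ml, of the xenobiotic metabolism list 11 of 12 genes fell, also adjusted over the list alone (median -1.83, camera adjusted p = 7.36e-06; adjusted p = 0.136 with an estimated correlation). UGT2B15, a glucuronosyltransferase, was at 19.1% of the control. Of 22 secreted hepatocyte proteins 20 fell (21 adjusted over the list alone; median -0.85, camera adjusted p = 5.99e-08; adjusted p = 0.136 with an estimated correlation). They included the hemoglobin scavenger HP (12.7%), the fibrinogen chain FGG (20.6%) and the coagulation factor F9 (22.4%). All 16 measured cholesterol biosynthesis genes fell, also adjusted over the list alone (median -1.27, camera adjusted p = 2.04e-08; adjusted p = 0.0686 with an estimated correlation). Lanosterol synthase LSS was at 27.0%, ACAT2 at 27.8% and MSMO1 at 36.5% of the control. Of the list of fatty acid oxidation and PPARA targets 14 of 17 fell and 1 rose, also adjusted over the list alone (median -0.87, camera adjusted p = 4.23e-05; adjusted p = 0.103 with an estimated correlation). CPT1A, which commits fatty acids to mitochondrial oxidation, was at 19.4% of the control, while ANGPTL4, a secreted lipase inhibitor, was the member that rose (6.3-fold). Of 15 bile acid genes 10 fell and 3 rose, the same adjusted over the list alone (median -0.94, camera adjusted p = 0.0178; adjusted p = 0.125 with an estimated correlation). CYP8B1, which sets the cholic acid share of bile acids, fell to 7.50%, and FGF19, a hormone that represses bile acid synthesis, rose 5.81-fold. Of 7 acute phase proteins 5 fell and 1 rose, also adjusted over the list alone (median -1.22, camera adjusted p = 0.0377; adjusted p = 0.294 with an estimated correlation). LBP, which binds lipopolysaccharide, was at 25.6% of the control. Of 21 oxidative phosphorylation genes 17 fell and 2 rose, the same adjusted over the list alone (median -0.40, camera adjusted p = 0.00192; adjusted p = 0.217 with an estimated correlation). SDHA, of the respiratory chain and citric acid cycle, was at 55.6% of the control.

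Other lists did not pass the camera test at 25 µg/ml although single members changed, with the same counts adjusted over the list alone. Of 12 NF-kB targets and cytokines 3 rose and 6 fell (adjusted p = 0.389). The chemokines CXCL2 and CXCL1 were at 30.6% and 32.8% of the control. Of 14 hypoxia and glycolysis genes 9 rose and 4 fell (adjusted p = 0.11), with the glucose transporter SLC2A1 3.69-fold higher. Of 10 interferon response genes 1 rose and 8 fell (adjusted p = 0.0937), and IFIT2 was at 42.2% of the control. Of 8 iron handling genes 3 rose and 4 fell (adjusted p = 0.922; median -0.079, mean 0.083, direction of the test down), with the transferrin receptor TFRC 5.35-fold higher. Of 17 selenoprotein genes 6 rose and 8 fell (adjusted p = 0.764). The thioredoxin reductase TXNRD1 rose 4.69-fold, and SELENOP, the plasma selenium carrier, fell to 25.2%. Of 11 copper handling genes 3 rose and 6 fell (adjusted p = 0.356), with the copper pump ATP7B at 30.4% of the control. Of 5 aryl hydrocarbon receptor targets 2 rose and 1 fell (adjusted p = 0.588; median -0.067, mean 0.29, direction of the test up), with CYP1A1 1.85-fold higher.

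At 25 µg/ml markers of other cell types moved in both directions. Of 6 cholangiocyte and progenitor markers 3 rose and 1 fell (median 0.59, camera adjusted p = 0.11). The keratin KRT7 rose 23.9-fold from 7.12 ± 0.15 to 11.70 ± 0.10 (SD, n = 3 each), KRT19 2.11-fold and SPP1 2.65-fold. Of 9 stellate cell and fibroblast markers 3 rose and 3 fell (adjusted p = 0.641). TAGLN, an actin-binding protein, was 7.02-fold higher and ACTA2, smooth muscle actin, was at 54.3% of the control. Of 4 endothelial markers 0 were called by limma (camera adjusted p = 0.722), and ENG, the member with the lowest p, had a log2 change of -0.15 (SE 0.066, adjusted p = 0.0626). Of 3 macrophage markers 1 rose, LYZ (1.5-fold; adjusted p = 0.526 for the list). Of 4 pluripotency and fetal markers 2 rose and 1 fell (adjusted p = 0.653), with LIN28B 1.57-fold higher and AFP at 90.1%. Counts adjusted over the list alone were the same for these 5 lists. Over the same arrays the mean log2 signal of the poly-A control RNAs added before labelling was 0.25 higher at 25 µg/ml than in the controls (SE 0.12). The difference between the 3' and 5' probe sets of ACTB was 0.26 ± 0.082 at 25 µg/ml and 0.45 ± 0.075 in the controls (SD, n = 3 each).

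**Figure D1:**
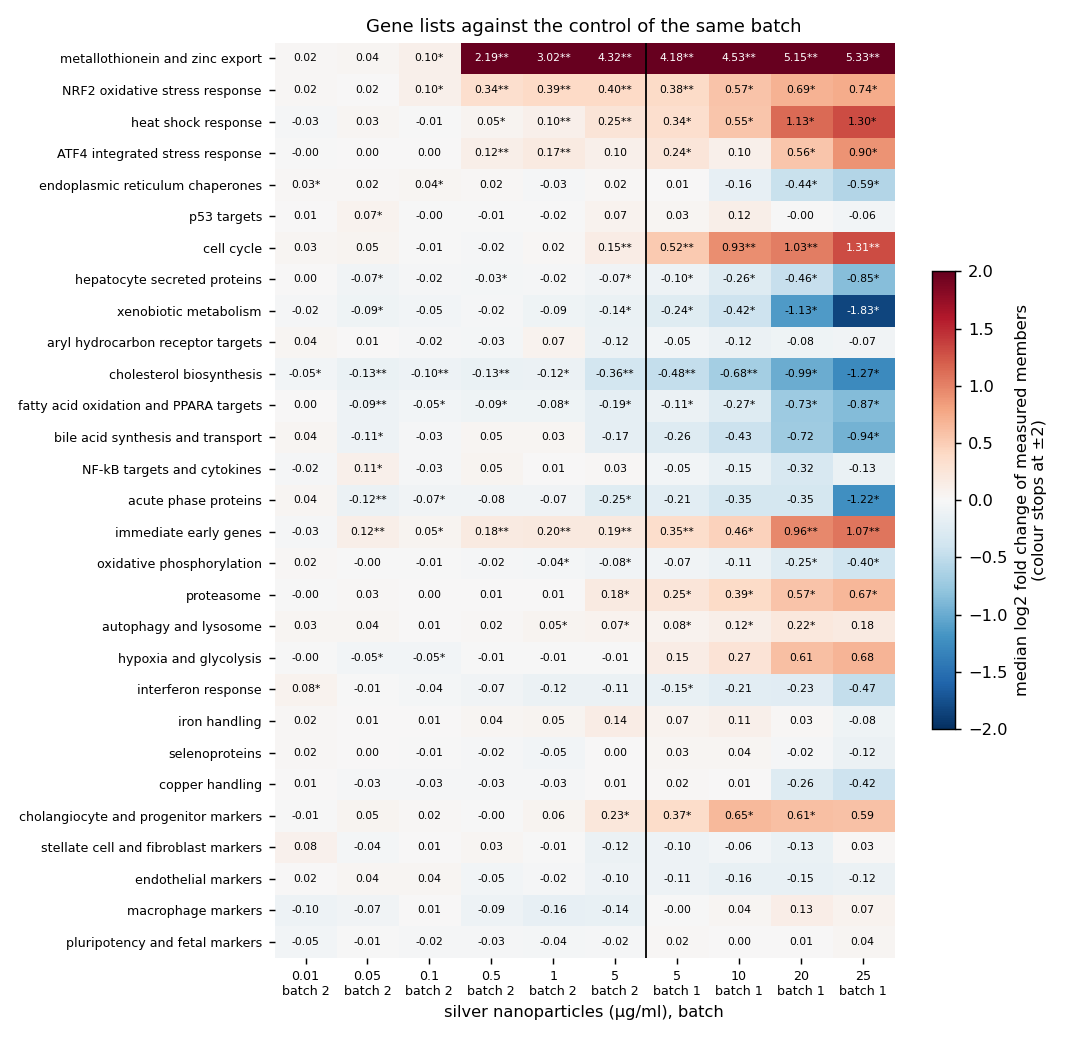
Median log2 fold change of the measured members of 29 gene lists (vertical axis) in each of the 10 comparisons with the control of the same batch (horizontal axis, µg/ml and batch; red higher, blue lower; 1 asterisk, camera adjusted p under 0.05; a pair, also with an estimated correlation). The metallothionein list has a median of 2.19 at 0.5 µg/ml and 5.33 at 25 µg/ml, and the cholesterol biosynthesis list lies below 0 in every comparison.

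In batch 1 MT1G rose 179-fold at 10 µg/ml and 270-fold at 20 µg/ml (limma log2 changes of 7.48 and 8.08, SE 0.058), approximate values since its signals of 14.05 and 14.64 lie near the top of the range. HMOX1 rose 17.9-fold and 44.8-fold, and HSPA6 29.4-fold and 143-fold. DNAJB1 rose 1.55-fold at 10 µg/ml and 3.51-fold at 20 µg/ml, and CDKN1A 1.28-fold and 1.61-fold. CYP3A4 fell to 34.1% of the control at 10 µg/ml and to 19.4% at 20 µg/ml. The largest falls at 10 µg/ml were in CTNNA2, a neuronal alpha-catenin (22.1%), ADH1A, an alcohol dehydrogenase (25.1%), LGALS2, a galectin (25.5%), and the complement component C6 (27.6%). At 20 µg/ml they were in ROBO2, a guidance receptor (11%), APELA, a peptide hormone (11.8%), ACOT12 (11.8%), AKR1D1 (12.7%) and DIO1 (12.8%).

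In all, limma called 5933 genes at 10 µg/ml (3014 higher, 2919 lower) and 8046 at 20 µg/ml (3650 higher, 4396 lower). At 20 µg/ml 22 of 23 heat shock genes rose (also adjusted over the list alone; median 1.13, camera adjusted p = 5.89e-13; adjusted p = 0.0938 with an estimated correlation). At 10 µg/ml 19 rose (19 adjusted over the list alone; median 0.55, camera adjusted p = 6.08e-10; adjusted p = 0.136 with an estimated correlation). Of the proteasome list 23 of 23 subunits rose at 10 µg/ml (also adjusted over the list alone; median 0.39, camera adjusted p = 5.74e-11; adjusted p = 0.0966 with an estimated correlation). All 16 cholesterol biosynthesis genes fell at both concentrations, also adjusted over the list alone (medians of -0.68 and -0.99; camera adjusted p = 2.81e-11 and 1.87e-08; adjusted p = 0.0361 and 0.0686 with an estimated correlation). Over the 4 exposed groups of batch 1 the limma F test called 8726 genes (69.5%).

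**Figure D2:**
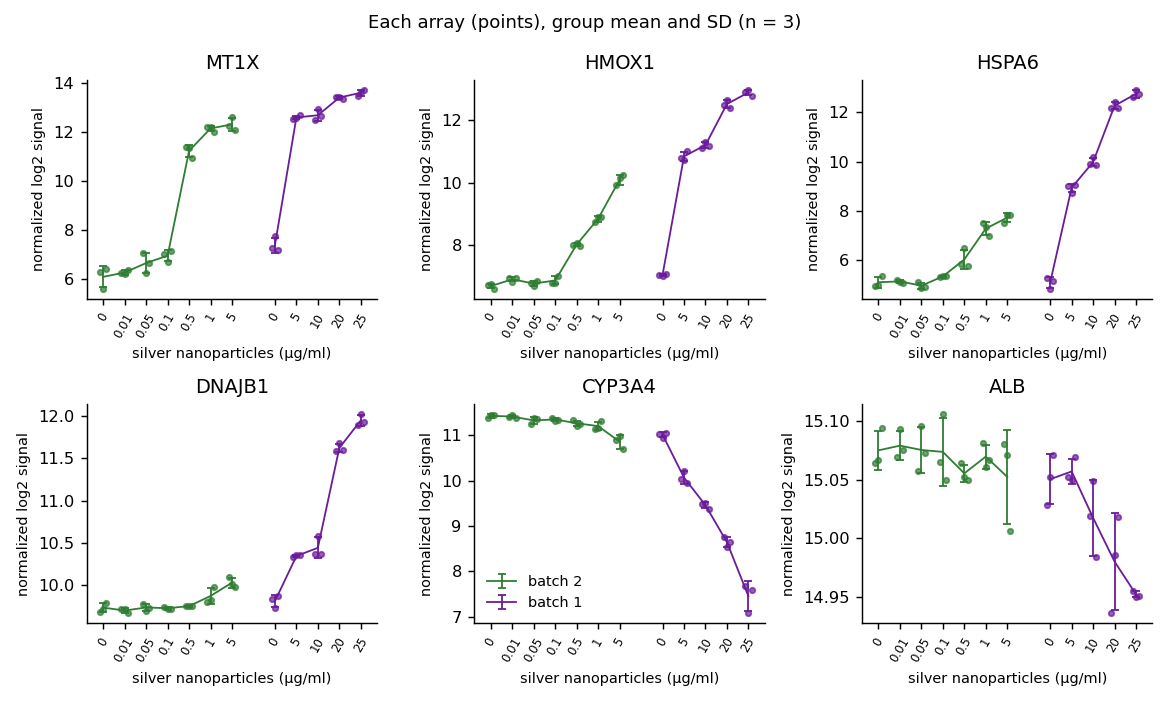
Normalized log2 signal of 6 genes (vertical axes, with separate scales) at each concentration of silver nanoparticles (horizontal axes, µg/ml, evenly spaced); points are single arrays, lines and bars are group means and SD (n = 3; green batch 2, purple batch 1). MT1X lies at 6.08 in the batch 2 controls and at 11.24 at 0.5 µg/ml, CYP3A4 falls from 11.01 to 7.45 over batch 1, and the ALB axis spans a narrow range near the top of the signal scale.

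At 5 µg/ml in batch 1 MT1G rose 114-fold from 6.57 ± 0.078 to 13.40 ± 0.068 (SD, n = 3 each). MT2A rose 18.8-fold from 10.01 ± 0.085 to 14.24 ± 0.066 (SD, n = 3 each). The exposed signal of MT2A lies near the top of the range, so its fold is approximate. HMOX1 rose 14-fold from 7.04 ± 0.033 to 10.85 ± 0.15, and HSPA6 14.3-fold from 5.10 ± 0.22 to 8.94 ± 0.17 (SD, n = 3 each). The largest falls were smaller: the galectin LGALS2 was at 36.7% of the control, CTNNA2 at 39.2%, the plasma glycoprotein HRG at 42.8%, SNX22, a sorting nexin, at 43.4%, and SERPINA7, the thyroxine-binding globulin, at 43.7%. CYP3A4 was at 52.0% (log2 change -0.94, SE 0.12), whereas CDKN1A had a log2 change of 0.031 (SE 0.058, adjusted p = 0.748), ALB of 0.0066 (SE 0.043, adjusted p = 0.93) and DDIT3 of 0.24 (SE 0.095, adjusted p = 0.0886).

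Limma called 2736 genes at 5 µg/ml in batch 1 (1601 higher, 1135 lower), of which 93 changed by at least 2-fold. The exposed and control arrays did not overlap for 37.3% of genes, where chance gives 10%. All 10 metallothionein and zinc export genes rose, also adjusted over the list alone (median 4.18, camera adjusted p = 7.45e-26). Of 23 NRF2 genes 17 rose (18 adjusted over the list alone; median 0.38, camera adjusted p = 1.54e-16), among them AKR1B10 (4.26-fold) and the aldo-keto reductase AKR1C1 (2.41-fold). Of 23 heat shock genes 15 rose (18 adjusted over the list alone; median 0.34, camera adjusted p = 9.71e-12; adjusted p = 0.109 with an estimated correlation). They included HSPA1B (4.34-fold) and CRYAB (2.84-fold). Of 21 cell cycle genes 12 rose (14 rose and 1 fell adjusted over the list alone; median 0.52, camera adjusted p = 5.3e-08). TTK was 3.78-fold, TOP2A, a topoisomerase, 2.74-fold and RRM2, a ribonucleotide reductase subunit, 2.62-fold higher. Of 12 immediate early genes 8 rose, also adjusted over the list alone (median 0.35, camera adjusted p = 8.03e-06), with EGR1 2.23-fold higher. Of 16 cholesterol biosynthesis genes 15 fell (16 adjusted over the list alone; median -0.48, camera adjusted p = 4.61e-16), with INSIG1, a brake on sterol synthesis, at 61.2% of the control. Of 16 endoplasmic reticulum chaperones 0 were called by limma, also adjusted over the list alone (median 0.013, mean -0.021, direction of the test down, camera adjusted p = 0.871), and SEL1L had the lowest p (log2 change -0.12, SE 0.044, adjusted p = 0.0605). Of 6 cholangiocyte and progenitor markers 4 rose, also adjusted over the list alone (median 0.37, camera adjusted p = 0.00779; adjusted p = 0.125 with an estimated correlation), with KRT7 2.71-fold and SOX9 1.37-fold higher. Replicate 3 of this group correlated least with its own group among the arrays of batch 1 (mean r across genes 0.995), and its poly-A control signal dap was 9.45, against 10.67 and 10.74 in replicates 1 and 2.

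Part of the genes called at 5 µg/ml turned at higher concentrations. CP, the copper-carrying ferroxidase ceruloplasmin, was 1.32-fold higher at 5 µg/ml and at 42.8% of the control at 25 µg/ml. Of the 2736 genes called at 5 µg/ml, 2543 were also called at 25 µg/ml, 2445 with the same sign and 98 with the opposite sign (75 higher and then lower, 23 lower and then higher). Independent lists of these sizes would share 929 genes of the same sign. Unchanged groups simulated around the mean of the same 3 controls shared 0 in each of 20 draws. Being centred on that mean, they leave out the error of the controls and cannot show what sharing the controls adds. Part of the excess may come from the shared controls, since 3 arrays cannot be split.

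At 5 µg/ml in batch 2, the top concentration there, the same leading genes rose. MT1G rose 87.3-fold from 6.67 ± 0.20 to 13.11 ± 0.070, MT1X 75.9-fold from 6.08 ± 0.43 to 12.32 ± 0.28, MT2A 24.2-fold from 9.31 ± 0.067 to 13.91 ± 0.061 (SD, n = 3 each). HMOX1 rose 10.7-fold from 6.68 ± 0.077 to 10.10 ± 0.16, and HSPA6 6.14-fold from 5.11 ± 0.22 to 7.73 ± 0.18 (SD, n = 3 each). LGALS2 (49.2% of the control), CTNNA2 (51.5%), PEG10, an imprinted gene of retrotransposon origin (53.7%), HRG (55.3%) and HES6, a transcriptional regulator (55.4%), showed the largest falls. CYP3A4 was at 67.3% of the control (log2 change -0.57, SE 0.065) and SULT2A1 at 65.0%. DDIT3 rose 1.28-fold (log2 change 0.36, adjusted p = 0.0136), but its mean was above the control in every exposed group of batch 2, with log2 changes of 0.17 to 0.31 at the lower concentrations that were not called. CDKN1A had a log2 change of 0.065 (SE 0.039, adjusted p = 0.29) and ALB of -0.023 (SE 0.036, adjusted p = 0.711).

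Limma called 1915 genes at 5 µg/ml in batch 2 (1052 higher, 863 lower), with 24 changed by at least 2-fold and no overlap of the arrays for 31.1% of genes, where chance gives 10%. The count was 1244 without replicate 3 of this group and 1069 with only the groups compared in the fit. All 10 metallothionein and zinc export genes rose, also adjusted over the list alone (median 4.32, camera adjusted p = 2.31e-35). So did 17 of 23 NRF2 genes (19 adjusted over the list alone; median 0.40, camera adjusted p = 4.05e-23) and 17 of 23 heat shock genes (18 adjusted over the list alone; median 0.25, camera adjusted p = 6.52e-12). Of 16 cholesterol biosynthesis genes 15 fell, also adjusted over the list alone (median -0.36, camera adjusted p = 2.07e-21), with ACAT2 at 70.1% and the mevalonate decarboxylase MVD at 72.3% of the control. Of 23 proteasome genes 15 rose (20 adjusted over the list alone; median 0.18, camera adjusted p = 4.09e-10; adjusted p = 0.136 with an estimated correlation). Of 21 cell cycle genes 8 rose and 1 fell, also adjusted over the list alone (median 0.15, camera adjusted p = 1.56e-04), and 6 of 12 immediate early genes rose (8 adjusted over the list alone; median 0.19, camera adjusted p = 2.52e-05). Of 12 xenobiotic metabolism genes 6 fell and 1 rose (7 fell and 2 rose adjusted over the list alone; median -0.14, camera adjusted p = 5.93e-04; adjusted p = 0.167 with an estimated correlation). HYOU1, the chaperone that was called higher (log2 change 0.17, adjusted p = 0.0271), was not called when all its probe sets were averaged.

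At 0.5 µg/ml in batch 2 the metallothioneins were already strongly raised: MT1X rose 35.8-fold from 6.08 ± 0.43 to 11.24 ± 0.24, MT2A 14.9-fold from 9.31 ± 0.067 to 13.21 ± 0.089, and MT1G 13.7-fold from 6.67 ± 0.20 to 10.44 ± 0.17 (SD, n = 3 each). HMOX1 rose 2.52-fold at 0.5 µg/ml and 4.48-fold at 1 µg/ml. Some heat shock genes were called and others not, and the difference between them was not tested. The 4 probe sets shared by HSPA1A and HSPA1B had log2 changes of 0.39 to 0.65 at 0.5 µg/ml and 1.15 to 1.46 at 1 µg/ml. The called members at 0.5 µg/ml, chosen after their values were seen, were HSPA1B and HSPA6. HSPA1B rose by 0.68 and 1.37 (SE 0.052) and HSPA6 by 0.92 and 2.17 (SE 0.16) at 0.5 and 1 µg/ml. DNAJB1 was not called at either concentration (log2 changes of 0.017 and 0.14, SE 0.049; adjusted p = 0.973 and 0.173). The genes that fell most were CYP26A1, which degrades retinoic acid (69.2% of the control at 0.5 µg/ml and 62.2% at 1 µg/ml), HES6 (68.9% and 68.6%) and, at 1 µg/ml, CDC20, an activator of the anaphase-promoting complex (69.7%), and ESRRG, an orphan nuclear receptor (70.6%). CYP3A4 had log2 changes of -0.17 and -0.23 (SE 0.065) that were not called (adjusted p = 0.469 and 0.0838).

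Limma called 57 genes at 0.5 µg/ml (41 higher, 16 lower) and 205 at 1 µg/ml (126 higher, 79 lower). Of 10 metallothionein and zinc export genes 9 rose at 0.5 µg/ml, also adjusted over the list alone (median 2.19, camera adjusted p = 5.18e-67), and 10 at 1 µg/ml (median 3.02). Of 23 NRF2 genes 12 rose at 0.5 µg/ml (15 adjusted over the list alone; median 0.34, camera adjusted p = 5.68e-38) and 14 at 1 µg/ml (18 adjusted over the list alone; median 0.39). Of 23 heat shock genes 2 rose at 0.5 µg/ml, also adjusted over the list alone (median 0.052, camera adjusted p = 0.0012; adjusted p = 0.193 with an estimated correlation), and 4 at 1 µg/ml (9 adjusted over the list alone; median 0.10, camera adjusted p = 1.91e-11). The counts varied when 1 array was left out, from 36 to 55 genes at 0.5 µg/ml and from 110 to 294 at 1 µg/ml. At 0.5 µg/ml 36 genes were called without control replicate 1 and 36 without exposed replicate 2. At 1 µg/ml 110 genes were called without control replicate 1, 121 without control replicate 2 and 294 without exposed replicate 3. Replicate 1 at 1 µg/ml correlated least with its own group in batch 2 (mean r 0.992), and 137 genes were called without it.

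Below 0.5 µg/ml MT1X, MT1G, MT2A and HMOX1 were not called over all genes. At 0.1 µg/ml 0 of 10 metallothionein and zinc export genes were called, and 3 were higher adjusted over the list alone (median 0.097, camera adjusted p = 0.00185; adjusted p = 0.172 with an estimated correlation). Of 23 NRF2 genes 0 were called, and 4 were higher adjusted over the list alone (median 0.10, camera adjusted p = 9.34e-09; adjusted p = 0.05 with an estimated correlation). MT1X had log2 changes of 0.18, 0.57 and 0.87 at 0.01, 0.05 and 0.1 µg/ml (SE 0.20; limma adjusted p = 0.999, 0.44 and 0.409), and MT2A of 0.093, 0.15 and 0.39 (SE 0.072; adjusted p = 0.999, 0.655 and 0.136). At 0.05 µg/ml limma called 11 genes, 8 higher and 3 lower, among them LTB, the cytokine lymphotoxin beta (1.56-fold), DUSP6, a phosphatase of ERK (1.34-fold), EFNB2, an ephrin ligand (1.27-fold). The lower genes were ACSS2, which makes acetyl-CoA from acetate (78.3%), AOC3, an amine oxidase (78.5%), and MVD (85.4% of the control). This count fell to 0 without control replicate 2 or without replicate 2 or 3 at 0.05 µg/ml, to 1 without replicate 1 at 0.05 µg/ml and to 3 without control replicate 1. It rose to 37 without control replicate 3. At 0.01 and 0.1 µg/ml limma called 0 genes, with 550 and 567 at an unadjusted p under 0.05. eBayes with trend and robust options called 1 and 15. At 0.1 µg/ml 2 were called with all 36 arrays in 1 fit and 1 after quantile normalization.

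The cholesterol biosynthesis list was shifted down in each of these groups although almost no member was called. Its median was -0.049 at 0.01 µg/ml (0 of 16 called, also adjusted over the list alone; camera adjusted p = 4.09e-04; adjusted p = 0.229 with an estimated correlation). It was -0.13 at 0.05 µg/ml (1 called, 12 adjusted over the list alone; camera adjusted p = 2.32e-15). It was -0.10 at 0.1 µg/ml (0 called, 3 adjusted over the list alone; camera adjusted p = 6.8e-13). Immediate early genes were shifted up at 0.05 µg/ml (median 0.12, 0 of 12 called, 5 adjusted over the list alone; camera adjusted p = 1.81e-06). At the same concentration 0 of 17 genes of the fatty acid oxidation list were called and 3 were lower adjusted over the list alone (median -0.095, camera adjusted p = 6.56e-08; adjusted p = 0.0367 with an estimated correlation). Of 7 acute phase genes 0 were called and 3 were lower adjusted over the list alone (median -0.12, camera adjusted p = 1.16e-04; adjusted p = 0.0361 with an estimated correlation). Another 6 lists passed at 0.05 µg/ml with the preset correlation and not with an estimated one. All these values share the same 3 control arrays, so a level of the list in the controls enters every group of batch 2.

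**Figure D3:**
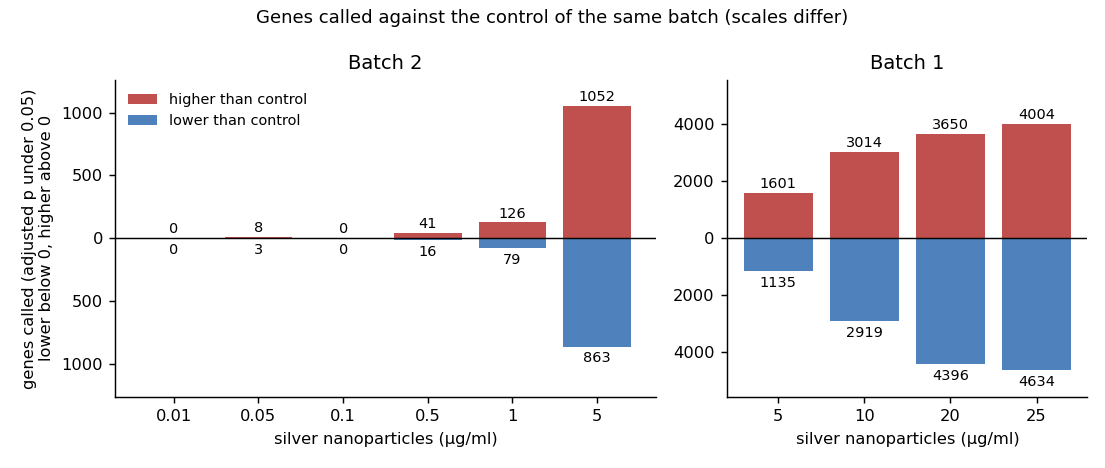
Number of genes called by limma at an adjusted p under 0.05 (vertical axes, with different scales) at each concentration of silver nanoparticles (horizontal axes, µg/ml) in batch 2 and batch 1 (red bars above 0, genes higher than the control of the same batch; blue bars below 0, lower). Batch 2 goes from 0 calls at 0.01 µg/ml to 1052 higher and 863 lower at 5 µg/ml, and batch 1 reaches 4004 higher and 4634 lower at 25 µg/ml.

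Over the 6 exposed groups of batch 2 the F test called 1366 genes (10.9%), and 887 without replicate 3 at 5 µg/ml. Counting each gene at the lowest concentration from which it stayed called with 1 sign, 49 genes of batch 2 began at 0.5 µg/ml (39 higher, 10 lower), 113 at 1 µg/ml (72 higher, 41 lower) and 1753 at 5 µg/ml (941 higher, 812 lower). In batch 1 2371 genes began at 5 µg/ml (1351 higher, 1020 lower), 2832 at 10 µg/ml (1283 higher, 1549 lower), 2408 at 20 µg/ml (887 higher, 1521 lower) and 1027 at 25 µg/ml (483 higher, 544 lower). Calls at successive concentrations of a batch share their controls.

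The exposure at 5 µg/ml was run in both batches, which gives a direct comparison of the response. MT1JP, a metallothionein pseudogene whose probe set may also bind other family members, rose more in batch 2 (log2 change 4.83) than in batch 1 (3.49), a difference of 1.34 (SE 0.16; limma adjusted p = 0.00406). MMP10 rose less in batch 2 (0.83) than in batch 1 (2.67), a difference of -1.84 (SE 0.23; adjusted p = 0.00406). Smaller in batch 2 were also the rises of CRYAB (0.53 and 1.51; adjusted p = 0.00175), TTK (0.97 and 1.92; adjusted p = 0.00406) and S100P, a calcium-binding protein (0.25 and 1.11; adjusted p = 0.00406). The signals of MMP10 and TTK lay under the filter value of 5.695 in the controls of both batches and in the exposed arrays of batch 2, as did that of MT1JP in the batch 2 controls, so these differences are approximate. PMAIP1, the proapoptotic NOXA, had log2 changes of 0.046 in batch 2 and 0.67 in batch 1 (adjusted p of the difference = 0.00523). Falls were smaller in batch 2 for SNX22 (-0.53 and -1.21; adjusted p = 0.00545), HP (-0.47 and -0.94; adjusted p = 0.026), CXCL2 (-0.044 and -0.60; adjusted p = 0.0263) and SLC2A14, a glucose transporter (-0.10 and -0.62; adjusted p = 0.0244).

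Of 12560 genes, 39 had a different effect in the batches, and the effect was larger in size in batch 1 for 38 of them. Across genes, which are not independent replicates, the log2 changes of the batches had a Pearson r of 0.851 and a Spearman rho of 0.721, and r was 0.811 without the metallothioneins. In the fit of the 12 arrays 1116 genes were called in both batches, 1113 of them with the same sign (99.7%, exact 95% interval 99.2 to 99.9%). This interval treats genes as independent and leaves out the spread between arrays. With 1 array left out, 4 of 12 percentages lay outside it. In the fits of each batch 796 genes were called higher in both batches and 574 lower in both, where independent lists would share 134 and 78. Another 4 had opposite signs, and the batches have separate controls. The control arrays themselves differed between batches, with 5013 genes called by limma (1516 higher and 3497 lower in batch 2) and a log2 difference of -1.3 for MT1X. The number of genes with different effects was 16 with no filter on dim probe sets, 74 with trend and robust options and 80 with all 36 arrays in 1 fit. It fell to 15 without batch 1 control replicate 3 or batch 2 replicate 1 at 5 µg/ml.

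**Figure D4:**
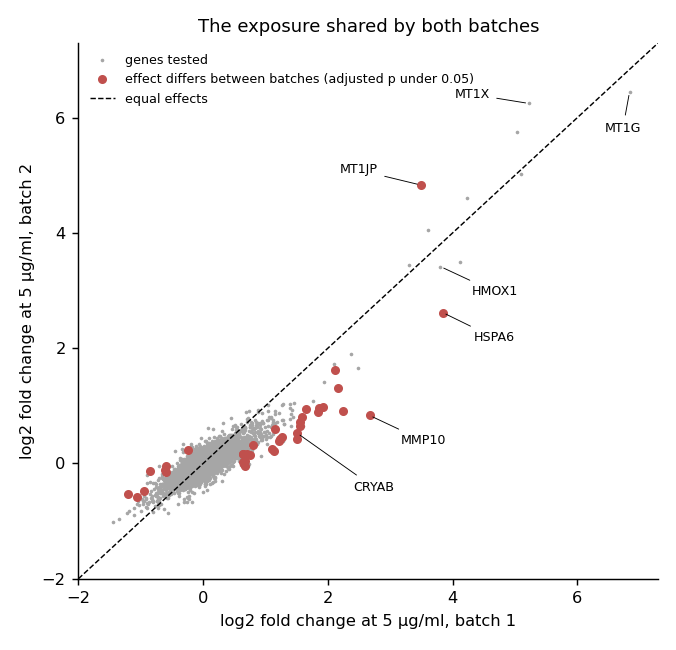
Log2 fold change of each gene at 5 µg/ml in batch 1 (horizontal axis) and batch 2 (vertical axis), each against its own controls (grey points, genes; red points, different effect at a limma adjusted p under 0.05; dashed line, equal effects). Most red points lie nearer to 0 on the batch 2 axis, as for MMP10 (2.67 and 0.83), with MT1JP (3.49 and 4.83) on the other side of the line.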

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

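The splits of the samples and the count of genes with a larger gap between the controls were planned before the results were seen, whereas the tests on ratios of summed effects, cell markers, ACTB and added control RNAs were chosen only after the result was seen.

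For 39 genes the effect of 5 µg/ml differed between the batches by limma's interaction term. The difference, batch 2 minus batch 1 on the log2 scale, was 1.34 for MT1JP, 0.68 for SNX22, 0.56 for CXCL2, 0.51 for SLC2A14, 0.47 for HP, -1.84 for MMP10, -0.98 for CRYAB, -0.94 for TTK, -0.85 for S100P and -0.62 for PMAIP1. The values of MT1JP, MMP10 and TTK are approximate, because their signals lay under the filter value in some of the groups. Of 100 groupings of the 12 arrays, after the additive effects of batch and concentration were removed, only the real 1 gave as many genes. The highest other gave 0. A share of 1 in 100 is the lowest that 100 groupings can give, so chance is unlikely for this count but not excluded. The groupings do not cover the spread between runs of a batch.

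In 38 of the 39 genes the effect was larger in batch 1. The batch 1 array at 5 µg/ml that correlated least with its group is only weakly argued against as the whole cause. Without it the ratio of summed batch 2 to batch 1 effects was 0.629 (SE 0.183), and 24 genes were still called. That ratio is under 1 by barely more than 2 SE. Leaving out each of the 12 arrays in turn gave ratios from 0.466 to 0.674. A different level of the control arrays alone stays open: 13 of the 39 genes differed more between batches in the controls than in the exposed arrays (33.3%, exact 95% interval 19.1 to 50.2%). That interval treats genes of the same arrays as independent, so it is too narrow to decide. A weaker response of batch 2 outside the metallothioneins is a candidate explanation. The ratio was 0.594 (SE 0.176) over 6695 genes called between 25 and 10 µg/ml in batch 1, without metallothioneins. These genes and their signs were taken from batch 1, so a response particular to that batch would lower the ratio. The slope of batch 2 on batch 1 effects was 0.615 over genes called at 5 µg/ml in batch 1. That of batch 1 on batch 2 effects was 1.21 over genes called in batch 2, each without metallothioneins. The medians of the metallothionein and NRF2 lists were not lower in batch 2. At 5 µg/ml the metallothionein list had a median log2 change of 4.18 in batch 1 and 4.32 in batch 2, and the NRF2 list 0.38 and 0.40. These medians were not tested between batches. MT1X began lower in the batch 2 controls (log2 difference -1.3), and some exposed metallothionein signals lie near the top of the range. Similar medians therefore cannot show that the response of these genes was equal. The batch differences in cells, particles and handling were not recorded in the labels and could not be told apart.

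At 25 µg/ml hepatocyte genes fell while KRT7 and MMP10 rose. A lower share of hepatocytes among the cells would raise the markers of the other cell types. Among the stellate cell and fibroblast markers ACTA2 fell (log2 change -0.88, SE 0.091) while TAGLN rose (2.81, SE 0.091). These genes can also change within a cell, so opposite signs cannot decide and a lower share stays open. More degraded RNA is only weakly argued against. The difference between the 3' and 5' signals of ACTB was lower at 25 µg/ml (-0.18). It was 0.45 ± 0.075 in the controls and 0.26 ± 0.082 in the exposed arrays (SD, n = 3 each). For GAPDH it was 0.114, 0.14 and 0.132 in the controls and 0.105, 0.079 and 0.139 at 25 µg/ml. ACTB was itself called from 10 µg/ml on, so its difference need not reflect RNA quality alone. A change within the hepatocytes themselves stays open and was not tested.

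At 25 µg/ml most genes were called, in both directions. Less mRNA in the same amount of RNA, hidden by the normalization, could make stable transcripts look higher, and would raise the added poly-A control RNAs as well. Their rise was 0.25 (SE 0.12), against a median of 0.51 for the 4004 genes called higher, so this is argued against as the whole cause. Rises of that size stay open, and 2087 of the 4004 genes exceeded the rise of the control RNAs plus 2 SE.

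Outside the genes tested, 963 of 1384 probe sets without a gene name (475 higher, 488 lower) and 743 of 1159 probe sets that match several genes (329 higher, 414 lower) were called at 25 µg/ml by limma.

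Each comparison with 3 arrays against 3 allows 10 splits, too few for a share under 0.05. The real split gave 2736, 5933, 8046 and 8638 genes at 5, 10, 20 and 25 µg/ml in batch 1, with a highest other of 0 in each, and 11, 57 and 1915 at 0.05, 0.5 and 5 µg/ml in batch 2, also with a highest other of 0. At 1 µg/ml the real split gave 205 and the highest other 1; in these comparisons 1 split, the real one, gave as many. At 0.01 and 0.1 µg/ml the real split gave 0 and the highest other 0, so all 10 were as large. For the F tests 1 of 100 groupings, the real grouping, was as large in each batch. The real grouping gave 8726 genes and the highest other 6671 in batch 1, and 1366 and 32 in batch 2. A share of 1 in 100 is the lowest that 100 groupings can give, so chance is unlikely but not excluded.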

How the results depend on the processing

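The alternatives were planned before the data were examined, except the fit without the array of each batch least like its own group, which was chosen only after the results were seen. Of 279 counts and correlations, 218 stayed within the tolerance (a factor of 1.5 for counts) and 61 did not; centring on medians moved 0 of them. Leaving out the array least like its group moved 0 of the 12 counts within a batch and was not run in this form for the difference between batches or the correlation. Of 276 onset counts 17 moved, among them 5 with trend and robust options, 5 when 1 array was left out and 3 with only the groups compared. Of 19 percentages of genes with the same sign 4 moved, all when 1 array was left out. Of 1392 list results 1343 kept their call, 38 lost it (29 of them with an estimated correlation), 11 gained it and 0 reversed. These list results cover only 25 µg/ml and 5 µg/ml in each batch. For lists at the other concentrations the estimated correlation was the only alternative given. Of 5968 results for named genes 5747 kept their call, 193 lost it, 27 gained it and 1 reversed: HYOU1 at 5 µg/ml in batch 2, with -0.0041 (adjusted p = 0.976) by the mean of all its probe sets. Beyond the thresholds and fits that change the number of genes or arrays, the cause was not tested. Requiring at least 2-fold left 93, 395, 1159 and 1697 genes at 5, 10, 20 and 25 µg/ml in batch 1. It left 0, 10, 13 and 24 at 0.05, 0.5, 1 and 5 µg/ml in batch 2, 1718 and 25 for the F tests and 5 for the difference between batches. An adjusted p under 0.01 left 1582 at 5 µg/ml in batch 1, 0, 35, 89 and 1029 at 0.05, 0.5, 1 and 5 µg/ml in batch 2, 681 for the F test of batch 2 and 10 for the difference. Without a filter there were 3 and 128 genes at 0.05 and 1 µg/ml, 16 for the difference and r = 0.788; the stricter filter gave 22, 309 and r = 0.882. The mean of all probe sets gave 20 at 0.05 µg/ml. Trend and robust options gave 1 and 69 genes at 0.01 and 0.05 µg/ml, 15 at 0.1 µg/ml, 105 and 409 at 0.5 and 1 µg/ml, and 74 for the difference. All 36 arrays in 1 fit gave 2 at 0.1 µg/ml and 80 for the difference. Quantile normalization gave 1 at 0.1 µg/ml, and fitting only the groups compared gave 0, 32, 45 and 1069 at 0.05, 0.5, 1 and 5 µg/ml in batch 2. For the F tests and the difference that fit equals the one reported and was not run. A block for the replicate number gave 4 at 0.05 µg/ml and 19 for the difference. The replicate numbers did not pair the arrays, with correlations of deviations at 25 µg/ml of 0.102, -0.093 and 0.287. Leaving out 1 array at a time gave 2072 to 2362, 4895 to 5491, 7416 to 7953 and 8156 to 8693 genes at 5, 10, 20 and 25 µg/ml in batch 1. It gave 0 to 0, 0 to 37 and 0 to 0 at 0.01, 0.05 and 0.1 µg/ml and 36 to 55, 110 to 294 and 1244 to 1828 at 0.5, 1 and 5 µg/ml in batch 2, 8268 to 8862 and 887 to 1479 for the F tests, 15 to 55 for the difference and r from 0.827 to 0.848. Moves over 1.5 times came without control replicate 1 (3 genes at 0.05, 36 at 0.5 and 110 at 1 µg/ml), control replicate 2 (0 at 0.05 and 121 at 1 µg/ml), control replicate 3 (37 at 0.05 µg/ml), each replicate at 0.05 µg/ml (1, 0 and 0), replicate 2 at 0.5 µg/ml (36), and replicate 3 at 5 µg/ml (1244, and 887 for the F test) in batch 2. For the difference they came without batch 1 control replicates 2 and 3 (18 and 15), batch 1 replicates 1 and 3 at 5 µg/ml (25 and 24), batch 2 control replicate 1 (16) and batch 2 replicates 1 and 2 at 5 µg/ml (15 and 24). Signals near the filter value of 5.695 and near the top of the scale limit what can be seen.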

Other observations

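All list tests in this part were chosen only after the results were seen, on 6 lists and 18 tests at 25 µg/ml and at 5 µg/ml in both batches, and the genes were chosen after their values were seen.

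Genes of complement and coagulation, made mainly in the liver, fell at 25 µg/ml: 27 of 28 measured members were called lower by limma (median log2 change -1.56; camera adjusted p = 0.0289 with an estimated correlation). KLKB1, which encodes plasma prekallikrein, had a log2 change of -3.34 (SE 0.11), the terminal complement component C6 of -3.32 (SE 0.069), the complement regulator C4BPB of -2.99 (SE 0.084) and F13B, a subunit of coagulation factor XIII, of -2.47 (SE 0.069). Genes of the urea cycle and amino acid breakdown also fell, 21 of 25 with 3 higher (median -0.93; adjusted p = 0.0635 with an estimated correlation). CPS1, which makes carbamoyl phosphate, had a log2 change of -2.97 (SE 0.076), OTC of -2.29 (SE 0.15) and ASS1 of -2.07 (SE 0.095), whereas KYNU, an enzyme of tryptophan breakdown, rose by 2.29 (SE 0.071) and HAL, which deaminates histidine, by 1.2 (SE 0.13). Of 17 aminoacyl-tRNA synthetase genes 9 rose and 4 fell (median 0.14, camera adjusted p = 0.21), with AARS1 at -1.50 (SE 0.079) and VARS1 at 1.12 (SE 0.082).

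Genes of matrix proteases, of their inhibitors and of epithelial attachment rose at 25 µg/ml. Of 10 matrix proteases and their inhibitors 9 rose and 1 fell (median 1.65; adjusted p = 0.0636 with an estimated correlation), with the collagenase MMP1 at a log2 change of 4.85 (SE 0.12), the urokinase PLAU at 4.02 (SE 0.091) and its receptor PLAUR at 2.98 (SE 0.14). The inhibitors TIMP1, TIMP2 and TIMP3 also rose (0.87, 1.95 and 1.32), and the protease PLAT fell (-0.18). Of 11 keratins, laminins and integrins 10 rose (median 1.48; adjusted p = 0.0638 with an estimated correlation; 2 members are also in the lists fixed earlier), with the laminin chain LAMB3 at 4.33 (SE 0.14), the integrin ITGA2 at 3.40 (SE 0.088) and KRT23 at 2.62 (SE 0.078). Of 17 genes that ERK signalling induces, among them inhibitors of the pathway itself, 15 rose and 1 fell (median 1.04; adjusted p = 0.0289 with an estimated correlation; 3 members are in the lists fixed earlier). The phosphatase DUSP5 had a log2 change of 3.78 (SE 0.11), PHLDA1 of 2.69 (SE 0.10), the receptor signalling inhibitor SPRY4 of 2.32 (SE 0.089) and SPRY1 of -0.55 (SE 0.070). At 5 µg/ml 15 of the 17 rose in batch 1 and 11 in batch 2 (adjusted p = 0.00462 and 0.00862 with an estimated correlation).

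Over 13 of the ERK-induced genes, those not named before the list was written, 11 rose and 1 fell (median 1.08, camera p = 0.03 with an estimated correlation, not adjusted). Over 23 genes of amino acid breakdown not named before, 19 fell and 3 rose (median -0.87, camera p = 0.0261 with an estimated correlation, not adjusted). Both lists were written after results from the same arrays had been seen, so these tests are void as support for a higher output of the ERK pathway or a lower capacity for amino acid breakdown. Neither was measured, no independent test was made, and both stay open.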
